A study of Danio rerio with 15 samples.

How the data were processed

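The log2 values of 15 one-colour Affymetrix zebrafish arrays were used as deposited by the authors, 1 value per probe set and array. The submitters' processing notes name GCRMA and Partek; the role of each and their versions were not given in the sources used here. Each array was hybridised with biotin-labelled material from 5 µg of total RNA per the labels. The values were neither centred per gene nor transformed again. Of 15617 probe sets, 115 Affymetrix control probe sets were left out and 15502 were tested. Among these, 10795 had 1 gene symbol, 135 had several and 4572 had none; genes are named only from probe sets with 1 symbol, which cover 8793 genes. Symbols came from the platform annotation of 2016 and were checked by Entrez number against the RefSeq gene names of zebrafish assembly GRCz12tu, which matched 10711 and updated 1. No genome build was named for the arrays and no coordinate was used.

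A beaker was the replicate, with n = 3 per group and 5 groups. A linear model with 1 mean per group was fitted to all 15 arrays in limma with moderated variances (10 residual and 2.37 prior degrees of freedom). The 11 comparisons were each treated concentration with control, the concentrations of each drug, the drugs at each concentration, the interaction of drug and dose, the mean of the SSRI groups with control, and any difference among the groups. P-values were adjusted within each comparison by Benjamini-Hochberg, with 0.05 as the threshold, and 95% intervals are those of the moderated fit and are not adjusted for the number of probe sets.

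The named genes of a comparison with control were the 12 largest rises and 12 largest falls among probe sets with 1 symbol that passed and in which all 3 treated arrays lay beyond all 3 control arrays. Other comparisons took 5 per direction, a comparison with no call took the 5 smallest p-values, and each gene list took up to 4 members that passed or, where none did, the 2 with the smallest p. The gene fkbp5 was always included. The 32 gene lists were written from general knowledge of zebrafish biology and needed at least 5 measured members; a gene with several probe sets was taken by the one with the highest mean. The camera test of limma compared the genes of a list with all others at a preset correlation of 0.01 and, as an alternative, with a correlation estimated per list, adjusted over all 128 list tests. The fry test of limma asked whether the genes of a list moved on balance in 1 direction, and its mixed form whether they changed in either direction; neither compares them with other genes. Groups of 3 were compared on GAPDH 3' minus 5' and acta1 3' minus 5' by exact two-sided permutation tests.

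The comparisons, lists, named-gene rule and most alternatives were fixed before the data were examined. These alternatives were median centring, quantile normalization, leaving out the 40% of probe sets with the lowest mean, a trended and robust prior, contrasts without moderated variances, array weights, a fold threshold of 1.5, fits of the compared groups alone, a replicate block and leaving out each array in turn. A fit with the GAPDH difference as a covariate and a fit without the 2 arrays with the largest difference (fluoxetine 25 replicate 3 and sertraline 250 replicate 2) were chosen after seeing the data. Similarity between responses was set against 100 simulations of unchanged groups that share 3 controls. These drew each probe set independently, with the same spread in every group.

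The model was tested on simulated data for fluoxetine at 25 µg/L against control with 15502 probe sets. It recovered 56.7% of 67 planted changes of 0.5 on the log2 scale, 92.5% of 67 changes of 1 and 95.5% of 66 changes of 2. Of 179 calls 16 were false, and an unchanged comparison gave 0 calls. This share of false calls is larger than the threshold on the adjusted p allows on average. The simulated arrays were drawn independently, with the same spread in every group. The real arrays of fluoxetine at 25 µg/L scatter more widely than those of the other groups. Recovery may therefore be lower, and false calls more frequent, in the real comparison than in this simulation. Computation used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.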

Results

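Gene expression was measured on 15 one-colour Affymetrix zebrafish arrays, each from RNA of the pooled larvae of 1 beaker. Larvae aged 72 h after fertilisation were kept for 96 h in 25 or 250 µg/L of fluoxetine or sertraline, 2 drugs of the selective serotonin reuptake inhibitor (SSRI) class, or in water without drug. Each of the 5 groups had 3 arrays (n = 3 beakers of about 100 larvae). The arrays gave 15502 probe sets after the Affymetrix control probe sets were set aside, with log2 values from 0.737 to 15.49 and array medians from 4.55 to 4.64. Pairs of arrays correlated across probe sets at r = 0.982 to 0.997, where probe sets are not independent replicates. The mean r within a group was 0.986 to 0.989 for the arrays of fluoxetine at 25 µg/L and 0.9947 to 0.9967 for those of the other groups. The model takes the same spread for all groups, so the wider scatter of this group enters the error of every comparison. The GAPDH 3' minus 5' control difference, a sign of RNA quality, averaged 1.66 in control, 1.96 and 1.45 at 25 and 250 µg/L fluoxetine, and 2.08 and 2.27 at 25 and 250 µg/L sertraline. Exact two-sided permutation tests against control gave p = 0.4 for each fluoxetine group and p = 0.1 for each sertraline group, and 0.1 is the smallest p that 3 against 3 arrays allow. Changes are given as log2 differences with the standard error (SE) of the fit, and adjusted p-values are from limma with Benjamini-Hochberg correction. The number of arrays limits the precision: the median 95% interval of a difference between 2 groups reached 0.24 to either side on the log2 scale.

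The comparison of fluoxetine at 25 µg/L with control asks which transcripts differ after exposure to the lower concentration. The largest change was in fkbp5, a co-chaperone that binds the glucocorticoid receptor and is induced by it: its value averaged 10.24 in control and fell by 4.99 ± 0.26 (SE, n = 3 per group), a fold of 31.8 (adjusted p = 1.05e-06). Several genes of the circadian clock fell, among them bhlhe41 by 2.41 ± 0.18, ciarta by 2.07 ± 0.12, per2 by 2.05 ± 0.11 and cry2 by 1.85 ± 0.11. The nuclear receptor genes rorcb and nr2f6b rose by 1.37 ± 0.12 and 1.04 ± 0.14, and the collagen chaperone gene serpinh1b rose by 2.06 ± 0.29. In all, 392 of 15502 probe sets passed the threshold, 134 higher and 258 lower, and 102 of them differed by 2-fold or more (15 higher, 87 lower).

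Further falls at 25 µg/L fluoxetine were dhrs13a.2 (-2.96 ± 0.42, adjusted p = 0.00195), the orphan nuclear receptor and immediate early gene nr4a1 (-2.41 ± 0.27), abcf2a (-2.25), odc1 (-2.12), which encodes the ornithine decarboxylase of polyamine synthesis, slc25a25a (-2.06), coq10b (-1.96), the small heat shock protein gene hspb6 (-1.94) and prelid3b (-1.91). Among the rises were mmrn2a (1.63 ± 0.18), ndrg1b (1.42 ± 0.10), zgc:193593 (1.36), ampd3b (1.27), an AMP deaminase gene, trim55b (1.11) and desi1b (1.096). The bile acid-responsive repressor gene nr0b2a rose by 1.80 ± 0.37 (adjusted p = 0.0212; the other nr0b2a probe set 0.77, not passed) and cyp24a1, which encodes the enzyme that inactivates vitamin D, by 1.34 ± 0.32 (adjusted p = 0.0483). The other probe sets of cyp24a1 (0.07) and desi1b (0.09) did not pass. All 3 treated arrays lay beyond all 3 control arrays for each of these genes because the naming rule required it. Chance gives this arrangement for 10% of probe sets. The calls of nr0b2a and cyp24a1 ended without fluoxetine 25 replicate 1 (adjusted p = 0.0662 and 0.112), without fluoxetine 25 replicate 2 (0.0908 and 0.15) and without control replicate 3 (0.0959 and 0.191), and that of cyp24a1 also without control replicate 2 (0.164).

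Of the 25 measured members of the circadian clock list, 7 fell, 0 rose and 18 did not pass; adjusted over the list alone, 10 fell and 2 rose. The camera test called the list lower (adjusted p = 2.23e-06), while adjusted p = 0.175 with an estimated correlation. The other per2 probe set, with values near 5.19 in control, gave -2.26 ± 0.44 (adjusted p = 0.0148); its call ended without fluoxetine 25 replicate 2 (0.0615), control replicate 2 (0.0735) or control replicate 3 (0.0657). Of the 22 glucocorticoid-responsive genes, 6 fell and 16 did not pass, and adjusted over the list alone 8 fell and 1 rose. They included fkbp5, cry2, the zinc finger gene klf9 (-1.68 ± 0.15) and the kinase gene sgk1 (-1.11 ± 0.18). The gene cry2 is also in the clock list and is counted in both. In 4 of the 6 fits that left out 1 array, 4 of these 6 falls were kept, and all 6 were kept only without fluoxetine 25 replicate 3. This list was called lower by camera (adjusted p = 8.53e-07), with adjusted p = 0.218 with an estimated correlation. The list of unfolded protein and integrated stress response genes had 4 members that fell and 30 that did not pass, 6 that fell and 1 that rose adjusted over the list alone. It included the mitochondrial folate enzyme gene mthfd2 (-1.79 ± 0.19) and the amino acid transporter subunit gene slc3a2b (-1.07 ± 0.09). The calls of atf3 and xbp1 both ended without control replicate 2 (0.168 and 0.14) or 3 (0.0809 and 0.191), that of atf3 also without control replicate 1 (0.0874) and that of xbp1 without fluoxetine 25 replicate 2 (0.123). Its camera call (adjusted p = 0.0254) was lost at adjusted p = 0.507 with an estimated correlation.

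In the heat shock list, 2 of 25 genes rose and 3 fell, and adjusted over the list alone 4 rose and 6 fell. The co-chaperone gene dnajb1b rose by 1.25 ± 0.15 with serpinh1b, and the mitochondrial chaperonin gene hspd1 fell by 0.91 ± 0.12; the median of the list was -0.05 and its mean 0.07, and camera gave the direction as lower (adjusted p = 0.612). Without control replicate 2, 1 of the 3 falls was kept, as hsf2 (0.0585) and hspa4b (0.0828) did not pass. Of the 29 photoreceptor and lens genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone): guca1c, which encodes a guanylate cyclase activator of cones, fell by 1.41 ± 0.12 and the cone phosphodiesterase gene pde6c by 0.81 ± 0.10. Both falls were kept without any 1 array, while the rises of gnat1, opn1mw2 and opn1sw2 were 2 without fluoxetine 25 replicate 3 and 1 without any other array. Without control replicate 2 the adjusted p was 0.131 for opn1mw2 and 0.0774 for opn1sw2, and without control replicate 3 it was 0.0734 for gnat1. Of 68 cell cycle and DNA replication genes, 4 fell and 64 did not pass (7 fell adjusted over the list alone), among them the histone-binding gene rbbp4 (-0.77 ± 0.10) and the replication helicase gene mcm2 (-1.11 ± 0.22, adjusted p = 0.016). The call of mcm2 ended without fluoxetine 25 replicate 2 (0.0571), control replicate 2 (0.0735) or control replicate 3 (0.0532). Those of dnmt1 and pcna also ended without control replicate 3 (0.0568 and 0.0842), which left 1 fall in the list, and without fluoxetine 25 replicate 2 (dnmt1, 0.0607) or 1 (pcna, 0.0594). The list had 9 falls without fluoxetine 25 replicate 3. The camera call of that list (adjusted p = 5.48e-05) had adjusted p = 0.524 with an estimated correlation. Of 42 neuronal genes, 1 rose, the transcription factor gene neurod1 (0.56 ± 0.08), 1 fell and 40 did not pass, with 2 higher and 10 lower adjusted over the list alone. The fall, of tubb5, ended without fluoxetine 25 replicate 1 (0.0907) or 2 (0.138) or control replicate 2 (0.158) or 3 (0.142), and there were 10 falls without fluoxetine 25 replicate 3. Camera called the neuronal list lower at adjusted p = 2.23e-06, with adjusted p = 0.524 with an estimated correlation. In the list of inflammatory genes, 1 of 34 fell, the NF-kappaB inhibitor gene nfkbiab (-1.25 ± 0.11), and 1 rose, as it did adjusted over the list alone. The rise, of cxcl12a, was kept only without fluoxetine 25 replicate 3 (adjusted p 0.0659 to 0.0961 without any other array).

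Lists of digestive organs were called higher by camera at 25 µg/L fluoxetine although none of their members passed on its own. The 19 exocrine pancreas genes had a median of 2.02 (adjusted p = 1.38e-08), the 22 yolk and lipoprotein genes 0.74 (0.00235) and the 30 hepatocyte genes 0.73 (0.000311), with adjusted p = 0.524, 0.684 and 0.697 with an estimated correlation. Adjusted over the list alone, 16 pancreas genes were higher, and 0 of the yolk and 0 of the hepatocyte genes. The elastase gene ela2l had the smallest p of the pancreas list at 2.62 ± 0.65 (adjusted p = 0.0582). Pancreas list means ranged from 4.34 to 5.58 in control arrays and were 7.63, 7.24 and 5.35 in fluoxetine 25 replicates 1, 2 and 3; replicate 3 also had the largest GAPDH 3' minus 5' difference of that group (2.36). Without fluoxetine 25 replicate 3, ela2l passed (3.49, adjusted p = 0.00198) and so did the antithrombin gene serpinc1 of the hepatocyte list (adjusted p = 0.0121, against 0.118 with it); ela2l also passed without control replicate 1 (3.11, adjusted p = 0.0416). The cardiac list (13 genes, adjusted p = 0.00369) and the xenobiotic metabolism list (26 genes, adjusted p = 0.0107) were also called higher, with 0 members past the threshold, 2 and 0 adjusted over the list alone, and adjusted p = 0.524 and 0.684 with an estimated correlation. Without fluoxetine 25 replicate 3, 15 pancreas, 12 yolk, 11 hepatocyte, 8 xenobiotic metabolism and 4 cardiac genes passed, all higher, among them slco1d1 (1.64, adjusted p = 0.00114) and tnnt2a (1.198, adjusted p = 0.000435). Leaving out the array with the lowest pancreas mean of its group favours such calls, so they are not separate support. The lowest array of this group lay below all control arrays for the yolk (6.20 against 6.28 to 6.85) and hepatocyte list means (5.76 against 5.84 to 6.57).

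Of the 15 measured genes for serotonin and other monoamines, 0 passed in limma at 25 µg/L fluoxetine, 0 adjusted over the list alone, and camera gave adjusted p = 0.374. The list also had 0 calls, over all probe sets and over the list alone, at 250 µg/L fluoxetine and at both sertraline concentrations (camera adjusted p = 0.654, 0.413 and 0.811). The mean of this list was 3.14 in control, while 40% of all probe sets had a mean under 3.90. A change in members with such low values may go unseen, so the absence of calls does not show that these genes were unchanged. No probe set carried the symbol of the serotonin transporter genes slc6a4a or slc6a4b (0 and 0 probe sets), the targets of both drugs. Among the stress axis and steroid synthesis genes, the glucocorticoid receptor gene nr3c1 rose at 25 µg/L fluoxetine (0.46 ± 0.09, adjusted p = 0.0204), and 12 of 13 did not pass; adjusted over the list alone 2 rose. Its call ended without fluoxetine 25 replicate 2 (0.0847) or control replicate 3 (0.0806). The mean of the stress axis list in control was 3.61, also under 3.90, so the same limit holds for that list. The other 2 probe sets of nr3c1 gave 0.06 and -0.07 and did not pass, while at 250 µg/L fluoxetine only the first of these passed (0.81, adjusted p = 0.0117), which also differed between the fluoxetine concentrations (0.75, adjusted p = 0.0466). Adjusted over all probe sets, 1 member fell and 0 rose in each of the lists of cholesterol synthesis, fatty acid oxidation and fasting, glucose metabolism, oxidative phosphorylation, cartilage, bone and matrix, and keratinocytes and ionocytes, and 2 fell in the oxidative stress list. Each of these 8 calls ended in at least 1 of the fits that left out 1 array. No member passed in the lists of fatty acid and triglyceride synthesis, lysosome, intestine, skeletal muscle, glia, pituitary and neuropeptide hormones, erythrocytes, ribosome biogenesis, proteasome and pigment cells, and camera called 0 of these 10 lists at this concentration. Without fluoxetine 25 replicate 3, 5 intestine, 3 lysosome, 3 glia, 2 ribosome biogenesis, 1 skeletal muscle, 1 pituitary and 1 erythrocyte gene passed, such as chia.2 (2.05, adjusted p = 0.00897) and slc1a2b (-0.44, adjusted p = 0.00545). Like those gained in the digestive lists, these calls rest on leaving out 1 array. Of ribosome biogenesis 1 gene also passed without fluoxetine 25 replicate 1 and 1 without control replicate 3.

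The count of 392 was 1034 without fluoxetine 25 replicate 3, 240 without control replicate 2 and 225 without control replicate 3; it was 1009 without the 2 arrays with the largest GAPDH 3' minus 5' difference, an exclusion chosen after seeing the data. A fit of the 6 arrays of this comparison alone gave 90.

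**Figure D1:**
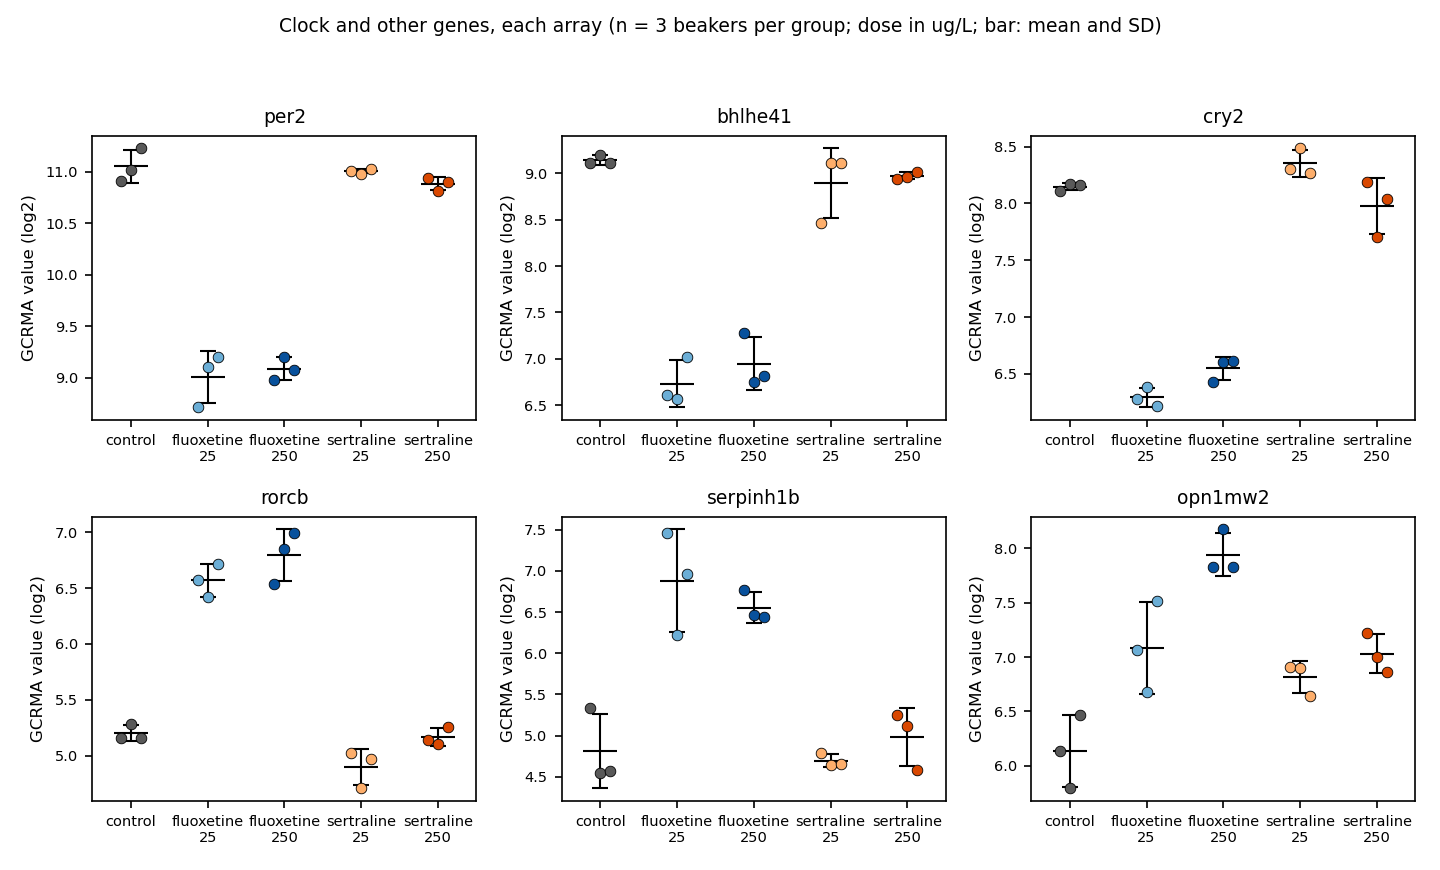
Log2 values of per2, bhlhe41, cry2, rorcb, serpinh1b and opn1mw2 in each array (points; n = 3 beakers per group), with the group mean and SD as bars and the groups along the horizontal axis. The 6 fluoxetine arrays sit between 8.72 and 9.20 for per2, below all control and sertraline arrays (10.81 to 11.23).

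Fluoxetine at 250 µg/L was compared with control to ask which transcripts differ after the higher concentration. The clock genes bhlhe41, per2, ciarta and cry2 fell by 2.196 ± 0.18, 1.97 ± 0.11, 1.62 ± 0.12 and 1.60 ± 0.11 (SE, n = 3 per group), the largest fall having a fold of 4.58 (adjusted p = 6.64e-05). Among genes that passed, the largest rise was in opn1mw2, a green-sensitive cone opsin, at 1.81 ± 0.21 (adjusted p = 0.000936), followed by serpinh1b at 1.74 ± 0.29 and rorcb at 1.59 ± 0.12. For fkbp5 the difference was -0.995 ± 0.26 and did not pass (adjusted p = 0.113). In all, 179 probe sets passed, 71 higher and 108 lower, with 32 at 2-fold or more (9 higher, 23 lower).

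Other falls at 250 µg/L fluoxetine were abcf2a (-1.47), the calcium-binding protein gene cabp5b (-1.44 ± 0.14), wdr76 (-1.30), the cryptochrome gene cry1b (-1.29 ± 0.12), wu:fb51h06 (-1.28), higd1a (-1.24), mthfd2 (-1.23 ± 0.19) and tefa (-1.11 ± 0.20), a clock output transcription factor gene. Rises were seen in mmrn2a (1.59 ± 0.18), ndrg1b (1.25 ± 0.10), ampd3b (1.07), trim55b (1.000), the cytokine signalling suppressor gene socs1a (0.97), calcoco1b (0.94), dnajb1b (0.90), the clock activator gene bmal1a (0.89 ± 0.17) and the growth factor gene hbegfa (0.88). Every treated array lay beyond every control array for these genes, as the naming rule required. Chance gives this for 10% of probe sets. The call of hbegfa (adjusted p = 0.0468) ended without any 1 of the 6 arrays (adjusted p 0.0547 to 0.191), and that of socs1a without fluoxetine 250 replicate 1 (0.18) or 2 (0.147) or control replicate 1 (0.0648), 2 (0.0626) or 3 (0.125). Without fluoxetine 250 replicate 1 the calls of abcf2a (0.0727), tefa (0.0593), serpinh1b (0.0635), calcoco1b (0.0505) and dnajb1b (0.0684) also ended. Without control replicate 2 the calls of tefa (0.0754), serpinh1b (0.0604), calcoco1b (0.0602), dnajb1b (0.0535) and bmal1a (0.0842) ended, without control replicate 3 those of abcf2a (0.0532), serpinh1b (0.0505) and dnajb1b (0.0527), and without control replicate 1 those of tefa (0.0609) and bmal1a (0.0931). Without fluoxetine 250 replicate 2 the calls of abcf2a (0.0512) and bmal1a (0.0624) ended, and without replicate 3 those of tefa (0.0547) and bmal1a (0.081).

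In the clock list 8 genes fell, 2 rose and 15 did not pass at 250 µg/L fluoxetine, and adjusted over the list alone 9 fell and 3 rose. Without any 1 array, 5 to 7 of the falls and 1 or 2 of the rises were kept. The other probe sets of per2 and tefa did not pass (-1.505 and -0.24), and neither did those of higd1a (-1.01) and socs1a (1.11). Camera called the list lower (adjusted p = 7.07e-06), with adjusted p = 0.175 with an estimated correlation. Of 29 photoreceptor and lens genes, opn1mw2 rose, pde6c (-0.91 ± 0.10) and guca1c (-0.64 ± 0.12) fell and 26 did not pass, with 4 higher and 2 lower adjusted over the list alone. Camera called that list higher (adjusted p = 0.00496), with adjusted p = 0.524 with an estimated correlation. In the heat shock list 2 genes rose and 2 fell, and 6 rose and 2 fell adjusted over the list alone. None of these 4 calls was kept without fluoxetine 250 replicate 1 (0.0535 to 0.092) or control replicate 2 (0.0535 to 0.12), and 1 without control replicate 3, that of hsf2. Of the neuronal genes neurod1 rose (0.64 ± 0.08) and 1 fell, as for 1 and 2 adjusted over the list alone; the list was called lower by camera (adjusted p = 0.00143), with adjusted p = 0.684 with an estimated correlation. Of the glucocorticoid-responsive genes cry2, which is also counted in the clock list, fell and 21 did not pass. Adjusted over the list alone 0 were higher and 2 lower, and the camera adjusted p was 0.483. The fall, of the neuronal gene tubb5, ended without fluoxetine 250 replicate 1 (0.137) or 2 (0.122) or control replicate 2 (0.133) or 3 (0.122). In the list of unfolded protein and integrated stress response genes, 2 fell, mthfd2 and slc3a2b (-0.50 ± 0.09), and 3 fell and 1 rose adjusted over the list alone. The call of guca1c ended without any 1 array other than fluoxetine 250 replicate 3 and control replicate 3 (adjusted p 0.082 to 0.105), and so did that of slc3a2b (0.0736 to 0.0983).

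The hepatocyte list (median 0.95, adjusted p = 2.95e-11), the yolk and lipoprotein list (0.85, 2.23e-06) and the pancreas list (1.13, 0.000108) were called higher by camera at 250 µg/L fluoxetine with 0 members past the threshold in each, and the adjusted p was 0.524, 0.524 and 0.684 with an estimated correlation. Adjusted over the list alone, 0 hepatocyte genes, 1 yolk gene and 0 pancreas genes were higher. Camera also called higher the lists of oxidative stress (adjusted p = 0.00167), fatty acid oxidation (0.00548), oxidative phosphorylation (0.00404), skeletal muscle (0.0338) and inflammation (0.042), and lower those of cell cycle (0.000519), ribosome biogenesis (0.00889) and pituitary hormones (0.0117). In the same order the adjusted p was 0.578, 0.524, 0.737, 0.684, 0.684, 0.524, 0.524 and 0.578 with an estimated correlation. Past the threshold over all probe sets was 1 cell cycle gene, rbbp4 as at 25 µg/L, and 0 genes of the other 7 lists. The pituitary gene gnrh2 passed without control replicate 1 (-1.31, adjusted p = 0.0271) and uts1 without fluoxetine 250 replicate 3 (-0.63, adjusted p = 0.0453). So did the muscle gene myog without fluoxetine 250 replicate 3 (1.112, adjusted p = 0.0465) and the hepatocyte gene f7 without fluoxetine 250 replicate 2 (0.52, adjusted p = 0.0301). Adjusted over the list alone, 8 cell cycle, 2 ribosome biogenesis and 2 pituitary genes were lower, 4 oxidative stress genes were higher and 2 lower, 2 fatty acid oxidation genes were higher, and 0 genes passed in the other 3 lists. The call of rbbp4 (-0.51 ± 0.10) ended without any 1 array other than fluoxetine 250 replicate 3 (adjusted p 0.0512 to 0.125). Of the 14 lists called, 9 were called without control replicate 3.

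The count of 179 was 74 without fluoxetine 250 replicate 1, and 118, 93 and 115 without control replicates 1, 2 and 3. It was 92 in contrasts without moderated variances, 276 with array weights and 61 in a fit of the 6 arrays alone.

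The comparison of both fluoxetine concentrations asks whether the response follows dose. The value of fkbp5 was higher at 250 than at 25 µg/L by 3.99 ± 0.26 (SE, n = 3 per group), a fold of 15.9 (adjusted p = 2.98e-05). Also higher at 250 µg/L were dhrs13a.2 by 2.93 ± 0.42, the zinc finger gene klf2a by 2.14 ± 0.36, sec23b by 2.104 ± 0.26, which encodes a coat protein of vesicles leaving the endoplasmic reticulum, nr4a1 by 1.98 ± 0.27 and klf9 by 1.23 ± 0.15. For the clock genes per2 and bhlhe41 the difference between concentrations was 0.08 (95% interval -0.17 to 0.33) and 0.21 (-0.18 to 0.61), with adjusted p = 0.692 and 0.478. In all, 39 probe sets passed, 38 higher at 250 µg/L and 1 lower, zgc:193593 (-0.73 ± 0.12), and 21 differed by 2-fold or more. The count was 155 without fluoxetine 25 replicate 1, 119 without fluoxetine 25 replicate 3 and 20 without fluoxetine 250 replicate 1. The call of klf2a ended without fluoxetine 25 replicate 2 (adjusted p = 0.0737) or fluoxetine 250 replicate 1 (0.105), 2 (0.082) or 3 (0.0795). That of zgc:193593 ended without fluoxetine 250 replicate 1 (0.105) or 3 (0.0956), and that of dhrs13a.2 ended without fluoxetine 250 replicate 1 (0.0501). The count was also 13 in contrasts without moderated variances, 25 with array weights, 18 with the GAPDH difference as a covariate, 113 without the 2 arrays with the largest GAPDH difference (both chosen after seeing the data) and 1 in a fit of the 6 arrays alone.

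Sertraline at 25 µg/L was compared with control with the same question. The value of fkbp5 fell by 2.19 ± 0.26 (SE, n = 3 per group), a fold of 4.57 (adjusted p = 0.0107), and klf9 fell by 1.23 ± 0.15. Falls were also found in pik3r3a (-1.46 ± 0.14), a regulatory subunit gene of phosphoinositide 3-kinase, in pfkfb4b (-1.23 ± 0.17), a regulator gene of glycolysis, and in slc3a2b (-0.68 ± 0.09). The immediate early gene egr4 rose by 2.01 ± 0.30 (adjusted p = 0.0402). In all, 10 probe sets passed, 1 higher and 9 lower, and 6 differed by 2-fold or more; the remaining calls were bzw1b (-1.02), tp53inp1 (-0.68), the autophagy kinase gene ulk1b (-0.55) and 1 probe set without a gene symbol (-0.65).

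All 9 falls at 25 µg/L sertraline were also calls in the same direction at 25 µg/L fluoxetine and 5 of them at 250 µg/L fluoxetine; the 3 control arrays are shared, so part of this may come from them. Of the 22 glucocorticoid-responsive genes 2 fell, fkbp5 and klf9, and 4 fell adjusted over the list alone; camera called the list lower (adjusted p = 0.00143), with adjusted p = 0.524 with an estimated correlation. Of 25 clock genes 0 passed in limma, 0 rose and 1 fell adjusted over the list alone, and camera gave adjusted p = 0.515. Camera also called higher the cartilage, bone and matrix list (adjusted p = 0.00421) and the pancreas list (0.0443), and lower the pituitary hormone list (0.00593) and the oxidative phosphorylation list (0.028). In the same order the adjusted p was 0.524, 0.769, 0.524 and 0.775 with an estimated correlation. None of the genes of these 4 lists passed over all probe sets, and adjusted over the list alone 1 pituitary gene was lower and 0 genes of the other 3 passed. The 5 list calls were 8 without sertraline 25 replicate 2, 8 without control replicate 1 and 3 without control replicate 3. The GAPDH 3' minus 5' difference of this group (1.95 to 2.17) lay above that of control (1.55 to 1.73), while the acta1 difference overlapped control (1.21 to 1.69 against 1.18 to 1.57).

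The count of 10 was 4, 1 and 5 without sertraline 25 replicates 1, 2 and 3, and 1 and 1 without control replicates 1 and 2. The call of fkbp5 ended without sertraline 25 replicate 2 (adjusted p = 0.0808), control replicate 1 (0.0624) or control replicate 2 (0.0632). The call of klf9 ended without the same arrays as fkbp5 (0.0808, 0.0624 and 0.0632). Those of egr4, ulk1b, bzw1b and tp53inp1 ended without any 1 of the 6 arrays (adjusted p 0.0527 to 0.328). That of pfkfb4b ended without any but sertraline 25 replicate 3 (0.0879 to 0.147), and that of slc3a2b without sertraline 25 replicate 2 (0.157) or 3 (0.122) or control replicate 1 (0.105) or 2 (0.106). The count was 4 under quantile normalization, 1 in contrasts without moderated variances, 25 with array weights and 0 in a fit of the 6 arrays alone. It was 16 without the 40% of probe sets with the lowest mean, 4 with the GAPDH difference as a covariate (list calls 10 in place of 5) and 6 without the 2 arrays with the largest GAPDH difference, the last 2 settings chosen after seeing the data.

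**Figure D2:**
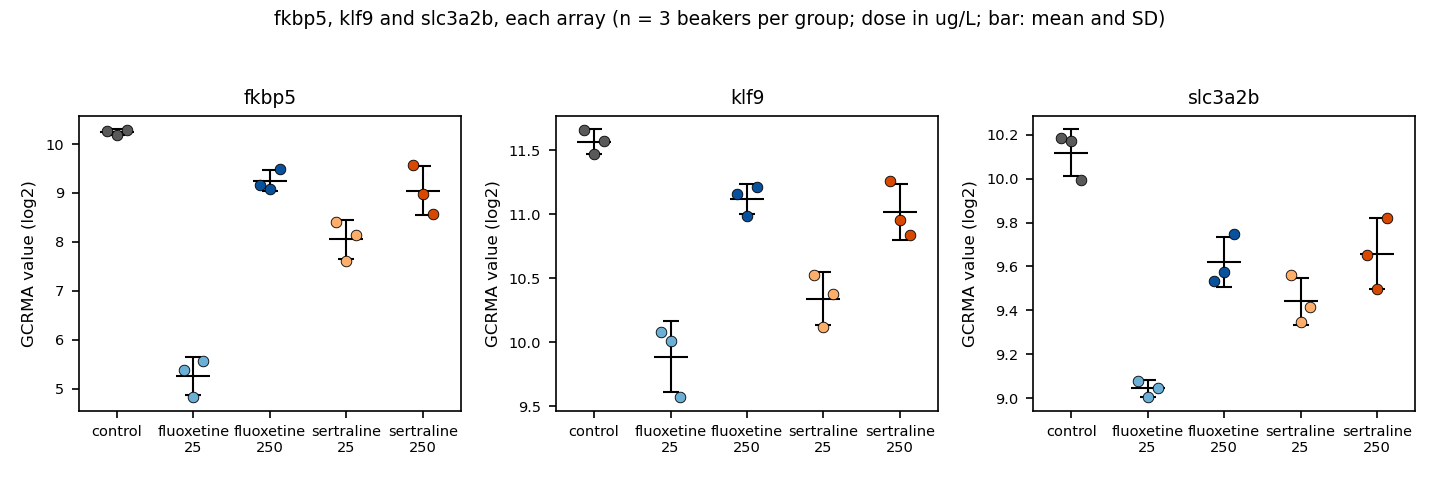
Log2 values of fkbp5, klf9 and slc3a2b in each array (points; n = 3 beakers per group), with the group mean and SD as bars and the groups along the horizontal axis. For fkbp5 the arrays sit between 10.18 and 10.28 in control and between 4.82 and 5.56 at 25 µg/L fluoxetine.

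Sertraline at 250 µg/L against control gave no gene past the threshold. The smallest p-values were those of socs3b (0.95 ± 0.14, SE, n = 3 per group; adjusted p = 0.0651), a suppressor of cytokine signalling, pik3r3a (-0.92 ± 0.14, 0.0651), the chitinase gene chia.1 (3.07 ± 0.50, 0.101), nr0b2a (2.25 ± 0.37, 0.101) and the intestinal alkaline phosphatase gene alpi.2 (0.88 ± 0.15, 0.134). In each of these 5 genes all 3 treated arrays lay beyond all 3 control arrays, which chance gives for 10% of probe sets. They were picked for their small p, which makes this arrangement likely. For fkbp5 the difference was -1.20 ± 0.26 (adjusted p = 0.25). The limma count was 0 of 15502 probe sets, with 983 at an unadjusted p under 0.05; it was 6 with a trended and robust prior, 28 with array weights, 8 without the 40% of probe sets with the lowest mean, 2 in a fit of the 6 arrays alone and 0 in contrasts without moderated variances. Of all probe sets, 97.2% had a 95% interval that lay within 2-fold of no change. This share includes probe sets with low values, in which a change may go unseen.

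Members of the intestine list were higher at 250 µg/L sertraline when adjusted over the list alone (5 of 24, and 0 lower), with 0 past the threshold over all probe sets. The list means were 5.59 to 5.65 in the treated arrays and 4.81 to 5.16 in control, and camera called the list higher (adjusted p = 7.07e-06), with adjusted p = 0.524 with an estimated correlation. The other lists called higher were fatty acid oxidation (adjusted p = 1.38e-08), yolk and lipoprotein (2.9e-08), ribosome biogenesis (4.88e-07), hepatocyte (2.46e-05), lysosome (4.96e-05), proteasome (4.96e-05), oxidative stress (8.6e-05), inflammation (0.000137), pancreas (0.00369), cartilage (0.00445) and oxidative phosphorylation (0.00889). Their adjusted p in the same order was 0.175, 0.524, 0.175, 0.684, 0.218, 0.524, 0.524, 0.524, 0.697, 0.524 and 0.765 with an estimated correlation. Adjusted over the list alone, 2 genes each of the fatty acid oxidation, yolk, lysosome and oxidative stress lists and 1 inflammatory gene were higher, and 0 genes passed in the other 6. Lists called lower were those of pituitary hormones (5.26e-05), neurons (0.00329) and glia (0.042), with adjusted p = 0.524, 0.684 and 0.507 with an estimated correlation. Adjusted over the list alone, 4 pituitary and neuropeptide genes, 0 neuronal genes and 1 glial gene were lower. For fabp1b.1, a fatty acid-binding protein gene of the yolk list, the difference was 2.91 ± 0.58, and for ehhadh of peroxisomal fatty acid oxidation 0.58 ± 0.12 (adjusted p = 0.25 for each). The GAPDH 3' minus 5' difference of this group ranged from 1.77 to 3.16 and lay above all control arrays. The count of 0 was 3 without control replicate 1, 1 without control replicate 2, where socs3b passed (1.13, adjusted p = 0.00522), and 1 without sertraline 250 replicate 3.

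**Figure D3:**
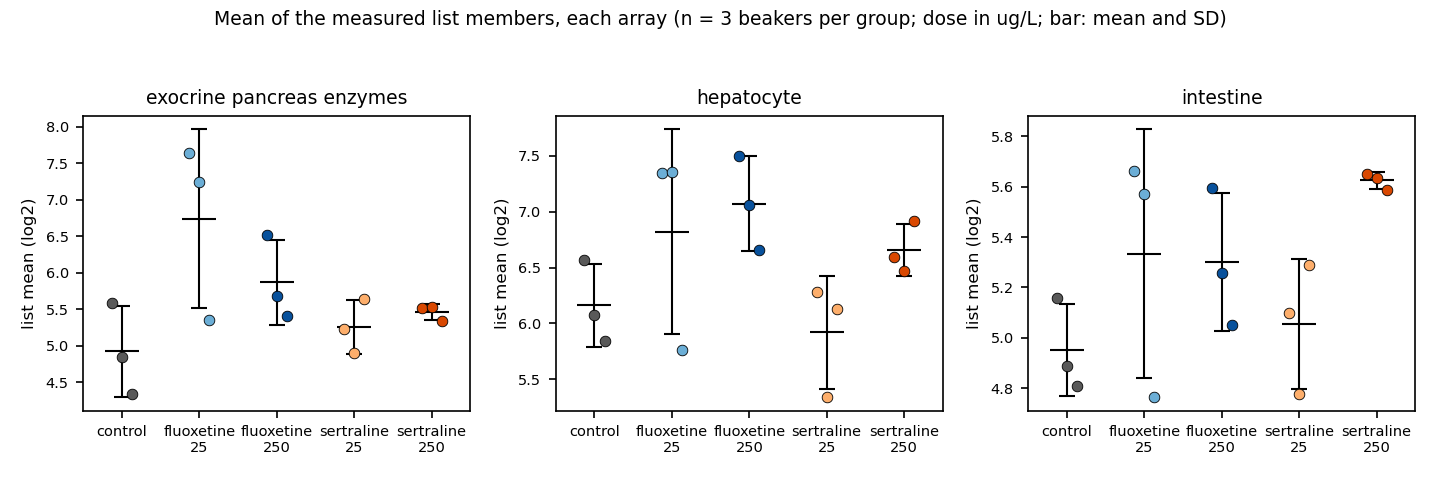
Mean log2 value of the exocrine pancreas, hepatocyte and intestine lists in each array (points; n = 3 beakers per group), with the group mean and SD as bars and the groups along the horizontal axis. The pancreas mean ranges from 5.35 to 7.63 within fluoxetine at 25 µg/L, and the intestine means at 250 µg/L sertraline (5.59 to 5.65) sit above those of control (4.81 to 5.16).

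Between the sertraline concentrations 0 probe sets passed in limma, with 754 at an unadjusted p under 0.05, 100 calls with array weights, 3 in a fit of the 6 arrays alone and 0 in contrasts without moderated variances. The smallest p-values belonged to bzw1b (0.89 ± 0.16, SE, n = 3 per group), the vitamin D hydroxylase gene cyp2r1 (0.75 ± 0.14), pcmt (-0.62 ± 0.11), si:ch73-141c7.1 (0.61 ± 0.11) and thoc6 (-0.38 ± 0.07), each with adjusted p = 0.322. For fkbp5 the difference between 250 and 25 µg/L was 0.99 ± 0.26 (95% interval 0.43 to 1.56, adjusted p = 0.494). The 95% interval lay within 2-fold for 97.6% of all probe sets, those with low values included.

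Fluoxetine and sertraline, 2 drugs of the same class, were compared at matched concentrations. At 25 µg/L, fkbp5 was higher with sertraline than with fluoxetine by 2.80 ± 0.26 (SE, n = 3 per group; 95% interval 2.23 to 3.36, adjusted p = 0.000141). The clock genes bhlhe41, cry2 and per2 were higher with sertraline by 2.16 ± 0.18, 2.05 ± 0.11 and 2.00 ± 0.11, and rorcb (-1.67 ± 0.12), ndrg1b (-1.57 ± 0.10) and serpinh1b (-2.18 ± 0.29) were lower. Further differences were dhrs13a.2 (2.33 ± 0.42), the insulin-like growth factor binding protein gene igfbp1b (-1.84 ± 0.34, adjusted p = 0.0161) and cyp24a1 (-1.59 ± 0.32, adjusted p = 0.0275). In all, 325 probe sets differed, 160 higher and 165 lower with sertraline, 57 of them by 2-fold or more (40 higher, 17 lower). With each array centred on its median the split was 196 higher and 102 lower, and with quantile normalization 138 higher and 121 lower. The other probe sets of per2 (1.81) and cyp24a1 (-0.22) did not pass. For klf9, pik3r3a and pfkfb4b the differences were 0.45 (95% interval 0.13 to 0.77), 0.34 (0.05 to 0.64) and 0.42 (0.06 to 0.78), and none passed (adjusted p = 0.101, 0.138 and 0.139). The 95% interval lay within 2-fold for 95.7% of all probe sets, those with low values included. The count was 820, 183 and 1007 without fluoxetine 25 replicates 1, 2 and 3, and 104, 134 and 137 without sertraline 25 replicates 1, 2 and 3. The call of cyp24a1 ended without fluoxetine 25 replicate 2 (0.0894) or sertraline 25 replicate 1 (0.0813), 2 (0.0947) or 3 (0.0654). That of igfbp1b ended without fluoxetine 25 replicate 2 (0.0638) or sertraline 25 replicate 1 (0.0699) or 2 (0.0685), and that of dhrs13a.2 without sertraline 25 replicate 1 (0.075) or 3 (0.056). The count was 509 with a trended and robust prior, 214 with array weights, 908 without the 2 arrays with the largest GAPDH difference and 54 in a fit of the 6 arrays alone.

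At 250 µg/L, bhlhe41, per2 and cry2 were again higher with sertraline, by 2.02 ± 0.18, 1.80 ± 0.11 and 1.42 ± 0.11 (SE, n = 3 per group), the first with a fold of 4.07 (adjusted p = 0.000168). The other per2 probe set gave 0.62 and did not pass. The alkaline phosphatase gene alpi.2 was higher by 1.399 ± 0.15 and wdr76 by 1.32 ± 0.13, while rorcb (-1.63 ± 0.12), ndrg1b (-1.55 ± 0.10), mmrn2a (-1.46 ± 0.18), serpinh1b (-1.57 ± 0.29) and crtac1a (-0.95 ± 0.21, adjusted p = 0.0498) were lower. For fkbp5 the difference was -0.20 ± 0.26, with a 95% interval of -0.77 to 0.36 (adjusted p = 0.863), and for pik3r3a and slc3a2b the intervals were -0.26 to 0.33 and -0.16 to 0.24. In all, 213 probe sets differed, 119 higher and 94 lower with sertraline, 25 of them by 2-fold or more (18 higher, 7 lower). The 95% interval lay within 2-fold for 96.7% of all probe sets, those with low values included. The count was 101 and 134 without fluoxetine 250 replicates 1 and 3, and 90, 102 and 107 without sertraline 250 replicates 1, 2 and 3. The call of crtac1a ended without those arrays (adjusted p 0.0541 to 0.173), and that of serpinh1b without fluoxetine 250 replicate 1 (0.0808) or 3 (0.0506) or sertraline 250 replicate 2 (0.0565) or 3 (0.0796). The count was 105 in contrasts without moderated variances, 668 with array weights, 48 with the GAPDH difference as a covariate, 138 without the 2 arrays with the largest GAPDH difference and 90 in a fit of the arrays compared.

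The interaction of drug and dose asks whether the step from 25 to 250 µg/L differs between the drugs. Only fkbp5 passed, 1 of 15502 probe sets: the step with sertraline minus the step with fluoxetine was -3.001 ± 0.37 (SE, n = 3 per group; 95% interval -3.80 to -2.21, adjusted p = 0.0375). The same difference was -2.43 ± 0.59 for dhrs13a.2, -2.07 ± 0.51 for klf2a, -0.55 ± 0.21 for klf9 and -0.14 ± 0.26 for bhlhe41 (adjusted p = 0.42, 0.42, 0.512 and 0.806). The count of 1 was 10, 0 and 16 without fluoxetine 25 replicates 1, 2 and 3, 0, 4 and 0 without fluoxetine 250 replicates 1, 2 and 3, and 0 without sertraline 25 replicate 1 or 3 or sertraline 250 replicate 2 or 3. The call of fkbp5 ended without fluoxetine 25 replicate 2 (-2.79, adjusted p = 0.111), fluoxetine 250 replicate 1 (-3.04, 0.143) or 3 (-2.88, 0.099), sertraline 25 replicate 1 (-2.83, 0.16) or 3 (-2.95, 0.191) and sertraline 250 replicate 2 (-2.97, 0.124) or 3 (-2.77, 0.08), as it did under quantile normalization, in contrasts without moderated variances and with the GAPDH difference as a covariate. The count was 2 with array weights and 9 without the 2 arrays with the largest GAPDH difference.

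The mean of the 4 SSRI groups was compared with control to ask what they share. Across the 4 groups, fkbp5 fell by 2.34 ± 0.20 (SE; 12 treated and 3 control arrays), pik3r3a by 1.29 ± 0.11, bhlhe41 by 1.26 ± 0.14, pfkfb4b by 1.06 ± 0.13 and the inositol kinase gene itpkcb by 1.02 ± 0.19. The mean rose for nr0b2a by 1.68 ± 0.29 (other probe set 0.71, not passed), for opn1mw2 by 1.08 ± 0.16, for slc35f6 by 0.60 ± 0.09 (other probe set -0.0009, not passed), for nr2f6b by 0.57 ± 0.11 and for slc25a55a by 0.53 ± 0.08. The mean hides differences between groups: for bhlhe41 it joins -2.41 and -2.196 with fluoxetine to -0.25 and -0.17 with sertraline. In all, 107 probe sets passed, 23 higher and 84 lower, and a test of any difference among the 5 groups called 432. The first count was 169 without fluoxetine 25 replicate 3, 67 and 71 without sertraline 25 replicates 2 and 3 and 62, 40 and 45 without control replicates 1, 2 and 3. In contrasts without moderated variances the first count was 48 and the second 221, and the second was 676 with array weights and 678 without the 2 arrays with the largest GAPDH difference. The second was 844 without fluoxetine 25 replicate 3 and 284 without fluoxetine 250 replicate 1. Without control replicate 3, the calls of nr0b2a (adjusted p = 0.172), itpkcb (0.165), nr2f6b (0.267), slc35f6 (0.0638) and slc25a55a (0.101) ended. Without control replicate 2 it was those of nr0b2a (0.0691), itpkcb (0.106), nr2f6b (0.0892), slc35f6 (0.0531) and opn1mw2 (0.072), and without control replicate 1 those of nr0b2a (0.069), itpkcb (0.167), nr2f6b (0.0882) and slc25a55a (0.0891). The calls of itpkcb or nr2f6b ended without any 1 of the 12 treated arrays other than fluoxetine 25 replicate 3, fluoxetine 250 replicate 3 and sertraline 25 replicate 1 (0.0530 to 0.0755).

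The responses of the 4 groups were set side by side across probe sets, which are not independent replicates. The log2 changes at 25 and 250 µg/L fluoxetine correlated at r = 0.63 (Spearman 0.47), and 43 rises and 80 falls were calls at both and 0 calls were opposite; no chance count is given, as the 3 control arrays are shared. In 100 simulations of groups without any change against shared controls, r averaged 0.50 and reached 0.53, because the same 3 control arrays enter both comparisons. The covariance of the fluoxetine responses was 0.0399, against a simulated mean of 0.0120 and a highest simulated value of 0.0134. The other pairs gave r = 0.37 for both drugs at 25 µg/L, 0.47 for both at 250 µg/L and 0.50 for the sertraline concentrations, 0.45 for 25 µg/L fluoxetine with 250 µg/L sertraline and 0.32 for the reverse, none above the highest simulated r. The covariance of 3 of these pairs nevertheless lay above the highest simulated one: 0.0153 for both drugs at 25 µg/L, 0.0235 for 25 µg/L fluoxetine with 250 µg/L sertraline and 0.0187 for both at 250 µg/L. It was 0.0132 for the sertraline concentrations and 0.01003 for 250 µg/L fluoxetine with 25 µg/L sertraline. The simulations drew each probe set independently with the same spread in every group, which real arrays do not follow. Leaving out 1 array moved r from 0.26 to 0.55 for both drugs at 25 µg/L. The highest simulated values are therefore too narrow a bound to decide whether a pair is more alike than shared controls make it.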

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

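The tests of light, hour, RNA degradation, beakers, fkbp5 between concentrations and splits were chosen only after the result was seen, while most alternative settings were planned. Thresholds were written before the tests of light, hour, RNA degradation and beakers were run, and after for the others. The step from 25 to 250 µg/L differed between the drugs for fkbp5, with a value of -3.001 on the log2 scale for sertraline minus fluoxetine, the only probe set past the threshold for that difference. That call ended in 11 of 22 alternative settings, so its size is better fixed than its place past the threshold.

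Of 25 clock genes, 7 fell at 25 µg/L fluoxetine, and 8 fell and 2 rose at 250 µg/L, while none passed over all probe sets with sertraline. With the GAPDH covariate, 100 percent of the 10 clock members called at either concentration stayed called, as did 16 of the 17 single calls. The mean GAPDH difference was 1.96 at 25 and 1.45 at 250 µg/L fluoxetine, against 1.66 in control. A covariate that moved in opposite directions could hardly remove falls at both concentrations. The falls therefore did not follow this measure of RNA quality, but the covariate fit adds little on degraded RNA. Less light or a weaker light response cannot be told apart: 5 light-induced genes had medians no higher than -0.327, but tefa among them is itself a called clock gene, and the 4 others had medians of -0.53 and -0.304 against the -0.3 written beforehand. A different hour of sampling cannot be told apart either, as the test gave 0.118 but only 3 of its 11 rhythmic genes lay above the lowest 40% of probe sets. The hour, the light each beaker received and the order of processing are not in the labels used here, and the sample numbers run in group order.

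The fall of fkbp5 was largest at 25 µg/L fluoxetine and smaller at 250 µg/L. The value of fkbp5 differed by 3.99 between the fluoxetine concentrations, while the 7 clock genes called at both differed by a median of 0.22 (1 of them past the threshold). These 7 genes were taken because they passed at both concentrations, which favours a small difference. It is also not known that fkbp5 would follow hour or light as they do. The comparison therefore cannot decide whether a shift in hour or light had a part in the fall of fkbp5. With the GAPDH covariate the change of fkbp5 at 25 µg/L fluoxetine was -4.987 ± 0.28 (adjusted p = 5.03e-06). Across the alternatives it ranged from -5.14 to -4.77, with adjusted p up to 0.00157. The mean GAPDH difference was 1.96 in this group and 1.66 in control, so the covariate could hardly remove such a fall. The arrays of this group (1.53 to 2.36) overlapped those of control (1.55 to 1.73). The fall therefore did not follow this measure of RNA quality, but the covariate fit adds little on degraded RNA. Why the lower concentration moved fkbp5 further stays open.

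Camera called the pancreas list higher in all 4 treated groups, and the hepatocyte and yolk lists in all but sertraline at 25 µg/L, without any member passing over all probe sets. None of these calls held with an estimated correlation (lowest adjusted p = 0.524). The comparisons share the 3 control arrays, so the recurrence across groups is not independent. The pancreas mean ranged over 1.25 within control. Its shifts were smaller at 250 µg/L fluoxetine (0.95) and at 25 and 250 µg/L sertraline (0.33 and 0.54). For the pancreas list variation between beakers may explain the calls, since its mean ranged over 2.29 within fluoxetine at 25 µg/L, more than its largest shift of 1.82 from control. For the intestine list this stays open: its shift of 0.676 at 250 µg/L sertraline exceeds the ranges in the treated (0.064) and control arrays (0.3497), but not the range of 0.899 within fluoxetine at 25 µg/L. The split with 836 calls for all SSRI groups (107 for the real one) and that with 36 between the fluoxetine concentrations (39 for the real one) set apart the same fluoxetine arrays, replicates 1 and 2 at 25 µg/L and 1 at 250 µg/L, which points to a structure of the samples. These arrays had the highest pancreas means, but which genes the splits called was not examined, and the source of the structure stays open.

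Relabelled arrays were counted for each result, with 10 splits for 3 against 3 arrays, too few for a share under 0.05. As many calls as the real split came from 1 of 10 splits for fluoxetine at 25 µg/L (392, highest other 3), 1 at 250 µg/L (179, highest other 1), 1 for sertraline at 25 µg/L (10, highest other 0) and 10 at 250 µg/L (0, highest other 0). Between concentrations it was 1 split for fluoxetine (39, highest other 36) and 10 for sertraline (0, highest other 1), and between drugs 1 at 25 µg/L (325, highest other 0) and 1 at 250 µg/L (213, highest other 2). For list calls, 4 splits reached the real 10 of fluoxetine at 25 µg/L (highest other 16), 3 the 14 at 250 µg/L (15), 5 the 5 of sertraline at 25 µg/L (14) and 1 the 15 at 250 µg/L (11). Of 100 splits of all arrays, 2 reached the 107 calls of all SSRI groups, 1 the 432 of any difference (highest other 3) and 6 the single call of the interaction (highest other 45, in a split that kept the 3 fluoxetine 250 arrays together under the other label, so that it holds the fluoxetine dose difference itself).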

How the results depend on the processing

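The tests with the GAPDH difference as a covariate and without the 2 arrays with the largest GAPDH difference were chosen only after the result was seen; all others were planned. No named gene value or list call was reversed in any setting, while the split of calls between drugs at 25 µg/L (160 higher, 165 lower with sertraline) turned to 196 and 102 with median centring and 138 and 121 with quantile normalization. The cause of a moved count was not tested. The 344 named gene values include genes that had not passed. A value counted as unchanged if it kept its side of the threshold. Unchanged were 340 with median centring, 335 with a trended and robust prior and 322 with quantile normalization. The number was 317 with the GAPDH covariate, 309 without the 2 arrays, 305 with array weights and 302 in contrasts without moderated variances. Fits of the compared groups alone left 270 of 334 unchanged, leaving out the lowest 40% 292 of 303 and leaving out 1 array 1905 of 2160. Calls were lost for 42 values in contrasts without moderated variances, 63 in fits of the compared groups alone and 231 on leaving out 1 array. Of 44 list calls, 0 stayed with an estimated correlation, 3 with fry, 39 with the GAPDH covariate, 41 with quantile normalization and 43 with the mean of all probe sets of a gene. Rescaling moved the median of a comparison by at most 0.065.

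With array weights the calls were 276 for fluoxetine 250, 25 for sertraline 25, 28 for sertraline 250, 25 between fluoxetine concentrations, 100 between sertraline concentrations, 214 and 668 between drugs at 25 and 250 µg/L, 2 for the interaction and 676 for any difference. In contrasts without moderated variances they were 92 for fluoxetine 250, 1 for sertraline 25, 13 between fluoxetine concentrations, 105 between drugs at 250 µg/L, 0 for the interaction, 48 for all SSRI groups and 221 for any difference. In fits of the compared groups alone they were 90 for fluoxetine 25, 61 for fluoxetine 250, 0 for sertraline 25, 2 for sertraline 250, 1 between fluoxetine and 3 between sertraline concentrations, 54 and 90 between drugs and 0 for the interaction. A trended and robust prior gave 6 for sertraline 250 and 509 between drugs at 25 µg/L; without the lowest 40%, sertraline 25 gave 16 and sertraline 250 gave 8; quantile normalization gave 4 for sertraline 25 and 0 for the interaction. At 1.5-fold or more, 246 remained for fluoxetine 25, 114 for fluoxetine 250, 170 and 110 between drugs and 62 for all SSRI groups. The GAPDH covariate gave 4 for sertraline 25, 18 between fluoxetine concentrations, 48 between drugs at 250 µg/L, 0 for the interaction and 10 list calls for sertraline 25. Without the 2 arrays, the calls were 1009 for fluoxetine 25, 6 for sertraline 25, 113 between fluoxetine concentrations, 908 and 138 between drugs, 9 for the interaction and 678 for any difference. List calls were 0, 0, 0 and 0 with an estimated correlation and 2, 1, 0 and 0 with fry for fluoxetine 25 and 250 and sertraline 25 and 250; the mixed form of fry, which takes changes in either direction, gave 19, 13, 1 and 8.

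Leaving out 1 array at a time gave 225 to 1034 for fluoxetine 25, 74 to 149 for fluoxetine 250, 1 to 7 for sertraline 25, 0 to 3 for sertraline 250, 20 to 155 between fluoxetine concentrations, 104 to 1007 and 90 to 173 between drugs, 0 to 16 for the interaction, 40 to 169 for all SSRI groups and 284 to 844 for any difference. List calls ranged from 9 to 13, 9 to 17, 3 to 8 and 13 to 15 in the same order of groups. Correlations of responses across genes, which are not independent replicates, ranged from 0.47 to 0.71 for the fluoxetine concentrations, 0.26 to 0.55 for both drugs at 25 µg/L, 0.33 to 0.58 for fluoxetine 25 with sertraline 250, 0.21 to 0.49 for the reverse, 0.39 to 0.60 for both at 250 µg/L and 0.40 to 0.65 for the sertraline concentrations.

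Replicate numbers were tried as a replicate block: 3 calls for sertraline 25 and 2 for sertraline 250, with 384 for fluoxetine 25 and 147 for fluoxetine 250. The numbers are not a pairing in the labels, and 30 same-number pairs correlated at -0.32 to 0.40 (mean 0.003), with 10 over 0.1 and 5 of 15 arrays closest to their own number.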

Other observations

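The tests proposed here were chosen only after the result was seen and none has been run. Fluoxetine separated the clock genes per2, bhlhe41 and cry2 from both control and sertraline at each concentration. At 25 µg/L, fkbp5, klf9, pik3r3a and slc3a2b fell with both drugs, each against the same 3 control arrays. For fkbp5 the change was -4.99 with fluoxetine and -2.19 with sertraline. At 250 µg/L fluoxetine, fkbp5 and klf9 did not pass in limma (adjusted p = 0.113 and 0.239), while pik3r3a and slc3a2b did.

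Fluoxetine may weaken the response of larvae to light, a possibility that the median of -0.327 in light-induced genes leaves open, as 1 of them is itself a called clock gene. Sampling fluoxetine and control beakers in parallel at several recorded hours, in light and in constant darkness, would separate a weaker light response from a shifted clock. If light is involved, the light-induced genes per2 and bhlhe41 should differ after a light pulse and not in darkness.

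Lower glucocorticoid signalling could lie behind the falls of fkbp5 and klf9, and the value of -4.987 for fkbp5 at 25 µg/L fluoxetine with the GAPDH covariate leaves this open. Whole-body cortisol in the same beakers, and exposure of larvae lacking a working glucocorticoid receptor, would test it. More concentrations between 25 and 250 µg/L, each with more beakers, would show whether the weaker fall at the higher concentration recurs.

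Differences in digestive development between beakers might account for the pancreas list, given a range of 2.29 in the pancreas mean within 1 group. Counting pancreas and liver area in imaged larvae of each beaker, with more beakers per group, would show whether the drug or the beaker carries the difference.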
